A study of Danio rerio with 10 samples.

How the data were processed

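RNA-seq libraries from the ventricles of 5 wild-type and 5 cited4a mutant adult zebrafish samples, all collected 3 days after ventricular amputation, were compared. Per the labels, polyadenylated RNA was the molecule sequenced. The labels do not say whether a library stems from 1 heart or from a pool, so the tests measure the spread between libraries, whatever each one holds.

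Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with HISAT2, counted with featureCounts and compared with DESeq2; the notes give no versions. Per the file headers, featureCounts 1.6.2 counted reads over exons per gene, without regard to strand and without the setting for paired ends, with the Ensembl release 106 annotation of GRCz11. The deposited per-sample values are raw read counts for 32057 genes. A deposited table of the authors holds normalized counts (signal) for 20292 genes in 8 libraries, without both replicates 3. Each of its columns equals the counts of that sample divided by 1 factor, for 100% of the genes listed. A second deposited table of the authors holds log2 fold changes with standard errors, and p-values with their adjusted values, from DESeq2. The deposited log2 fold changes have the sign of wild type over mutant, as read from the deposited normalized counts. Reads that fit several paralogs, or overlapping genes on opposite strands, cannot be told apart in such counts. No sequence reads or genome were used here, so neither the allele nor variants linked to it were examined.

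Gene names came from the deposited table (20231 genes) and, for 9857 others, from a reference table of gene names. Of the names, 552 were held by more than one identifier, and such genes carry their identifier. All 10 count columns were mapped to their samples, and no pair of the 20 within-group pairs of libraries was a duplicate: the chi-square per degree of freedom lay between 59.6 and 380. Totals were 53645645 to 73990485 counts per library, in which the mates of a pair would count separately if the libraries are paired-end.

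The main test was edgeR 4.0.16 with TMM scaling, its default expression filter by group, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment over 18946 genes, two-sided, with a threshold of 0.05 (R 4.3.3). Scaling by library size alone would move the median change of all genes to 0.12 on the log2 scale, while with TMM it was near 0; all changes are relative to TMM. Alternatives were DESeq2 1.42.0, limma-voom 3.58.1 with sample quality weights, RLE and upper-quartile scaling, TMM without haemoglobin and mitochondrial genes, no filter, a filter of 1 CPM in 5 libraries, a fit that was not robust, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. These and the comparison, lists and naming rule were written before the data were examined. Chosen afterwards were the fits on 8 libraries without both replicates 3, counts at an unadjusted p under 0.05, the tests by whole chromosome, the exact permutation of list means, and the block combined with an estimated correlation or with fry.

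The mutated gene was also tested by an exact two-sided permutation of its CPM over the 252 labellings of 5 against 5. There were 34 gene lists, written before the data were examined, and the spelling of list symbols was matched to the identifiers before any test. They were tested by camera on voom log2 CPM with a preset correlation of 0.01, and also by camera with an estimated correlation, by fry, and by exact permutation of the mean log2 CPM (prior count 2). The medians of lists are of voom log2 changes, without sample weights. Members called were counted over all genes and adjusted over the list alone. Some genes belong to more than one list, such as vegfaa, ldha and pfkfb3, so the lists are not independent. Position was tested by Fisher's exact test in windows of 5 Mb holding 10 or more tested genes.

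The text names cited4a, cited4b and cited2; the 12 genes higher and the 12 lower in the mutant with a mean log2 CPM over 1, a given name, and every library on its group's side of the other group's mean, filled by smallest adjusted p because edgeR called none; for each list, its called members or, with none called, the 2 most abundant; and always myl7, vmhc (now myh7), nppa, nppb, gata4, runx1, mki67 and pcna. Other genes named were chosen after their values were seen: the members that passed adjusted over a list alone and are not in the rule, tpx2, tacc3, nkx2.5, nr4a3, tcap, esrra, acta1b, hmox1a, cxcl12a, ptgs2b, klf2a, klf2b, flt1, the hsp70 and hsp90aa1.1 genes, actc1a, those without a given name, and the genes of the cluster on chromosome 19 other than tapbp.1, mhc1uka and hsd17b8.

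Samples of the same replicate number deviated together from their group means, with correlations of 0.396, 0.150, 0.598, 0.265 and 0.102 for replicates 1 to 5. Since each is over 0.1, the numbers were taken to pair the samples, on the evidence of the values and not of the labels. For replicates 2 and 5 a library of another number correlated more, at 0.203. The main test was kept without the block, as planned.

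The tests of edgeR, DESeq2, weighted limma-voom, camera and fry were tried on simulated counts drawn from the means and library sizes of these 10 libraries, with 200 genes changed. EdgeR recovered 33% of 2-fold and 95% of 4-fold changes, with 4 unchanged genes called. DESeq2 recovered 57% and 98%, with 54 unchanged genes called, and weighted limma-voom 32% and 93%, with 3. A simulated list of 60 genes changed 1.5-fold was called by camera with the preset and with an estimated correlation and by fry. With the preset, 0 unchanged lists were called. Simulated genes were drawn independently of each other, while the estimated correlation within the real lists reached 0.935. The simulation thus does not show how often lists of correlated genes are called wrongly or missed. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.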

Results

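Polyadenylated RNA was sequenced from ventricles of adult zebrafish 3 days after amputation of part of the ventricle, a time at which the heart has begun to regenerate. There were 5 wild-type libraries (AB* background) and 5 cited4a mutant libraries, all from fish 6 months to 1 year old. Between 53645645 and 73990485 reads per library were assigned to genes, counted without pairing of mates, and 18946 genes passed the expression filter and were tested. At this depth a gene at the median had a biological coefficient of variation of 0.32 between replicates, so for such a gene replicate spread rather than counting error set the precision. Gene levels below are TMM-scaled CPM, counts relative to the effective library size, given as mean ± SD of 5 libraries, and changes are log2 fold changes of mutant over wild type from edgeR, ± standard error.

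The libraries did not separate by genotype on the first principal component, which held 31.3% of the variance of the 500 most variable genes and set wild type replicate 3 apart at -41.78. On the second component, with 25.8%, wild type replicates 3, 4 and 5 lay between -25.5 and -23.94, while mutant replicates 4 and 5 lay at 24.62 and 36.04. The groups overlapped there, with wild type replicate 2 at 7.38 above mutant replicates 1 (-2.94) and 3 (3.45), although the mutant was higher in 5 of 5 pairs of the same replicate number. The labels do not pair the libraries, and the values did so only weakly for replicates 2 and 5. Mitochondrially encoded transcripts took 17.2% of counts in wild type replicate 3 and 19.7% in mutant replicate 3, against 10.6% to 13.8% in the other libraries. The same 2 libraries held relatively more reads of short genes: the median deviation of the genes in the lowest quartile of length minus that in the highest quartile was 0.400 and 0.318 on the log2 scale, against -0.128 to -0.003 elsewhere.

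**Figure D1:**
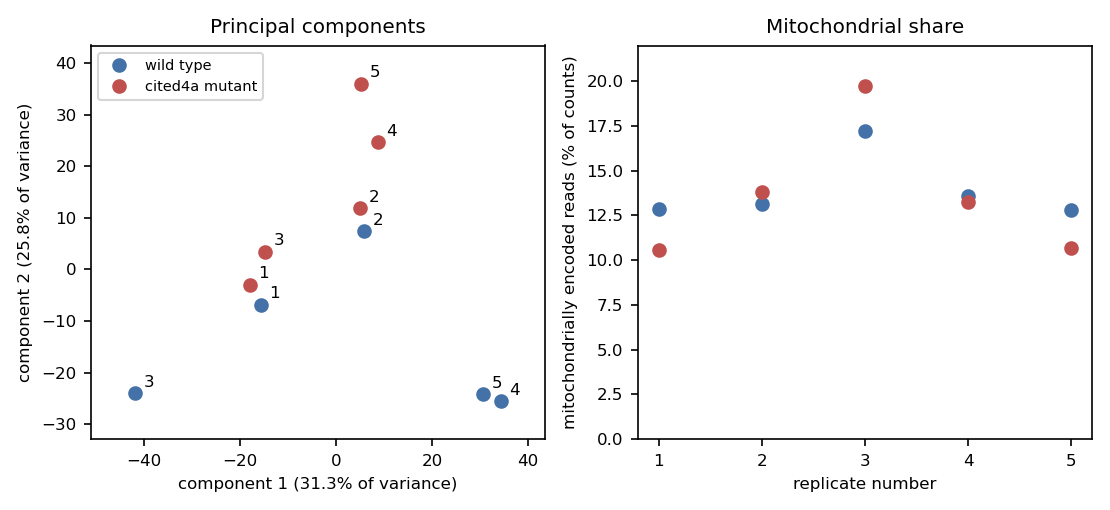
Left, the first and second principal components of log2 CPM of the 500 most variable genes, 1 point per library with its replicate number. Right, mitochondrially encoded reads as a percent of counts, by replicate number; both libraries numbered 3 (17.2% and 19.7%) lie above all others.

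The comparison asks what loss of cited4a, a CITED family transcriptional coregulator that binds p300 and CBP, changes in the injured ventricle, with cardiomyocyte dedifferentiation and proliferation as the named interest of the series. Transcripts of cited4a itself (ENSDARG00000035990, GRCz11 chromosome 19, 15851226 to 15855427) were at 59.2 ± 26.4 CPM in wild type and 60.3 ± 29.4 CPM in the mutant, a log2 change of 0.03 ± 0.37. An exact two-sided permutation test of the 5 against 5 values gave p = 0.960, where 0.00794 is the smallest p this design allows. Each library held between 1496 and 5191 reads of the gene, so depth did not limit this comparison. The sign of that small change turned with the weighted limma-voom fit and without both replicates 3. The labels do not describe the lesion of the allele, and counts per gene cannot show one. Of the paralogs, cited2 (ENSDARG00000030905) was at 19.03 ± 9.54 CPM in wild type and 8.13 ± 2.13 CPM in the mutant (-1.23 ± 0.40, edgeR adjusted p = 0.624). Only wild type replicate 3, at 4.22 CPM, overlapped the mutant libraries (5.91 to 10.54 CPM), and the other wild-type libraries lay between 18.04 and 29.8 CPM. The authors' DESeq2 comparison, without both replicates 3, gives cited2 an adjusted p of 2.42e-06. In edgeR its adjusted p stayed at 0.0990 or above when single libraries were left out. The other paralog, cited4b (ENSDARG00000101009), was at 7.63 ± 3.31 CPM and 16.2 ± 10.1 CPM (1.08 ± 0.45, edgeR adjusted p = 0.715). Across the 8 tested genes of the CITED family and p300/CBP list the median change was 0.04 and no member passed the threshold, either over all genes or adjusted over the list alone. Its most abundant other member, ep300b, was at 55.0 ± 4.69 CPM and 57.3 ± 4.195 CPM.

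Il11a, a cytokine of the interleukin-6 family, had the smallest p of all genes: 36.0 ± 12.8 CPM in wild type against 5.03 ± 1.88 CPM in the mutant, a change of -2.84 ± 0.34 (ENSDARG00000037859, chromosome 16, 12611362 to 12617155). Every mutant library (2.67 to 7.35 CPM) lay below every wild-type library (16.8 to 51.2 CPM). Vegfaa, a vascular endothelial growth factor (ENSDARG00000103542, chromosome 16, 4287542 to 4317879), was at 82.7 ± 12.4 CPM and 36.0 ± 7.08 CPM (-1.201 ± 0.17), and adrb2b, a beta-2 adrenergic receptor (ENSDARG00000054510, chromosome 21, 35078766 to 35082715), at 8.42 ± 2.70 CPM and 2.31 ± 0.86 CPM (-1.87 ± 0.30). Mutant and wild-type libraries did not overlap for either gene. In edgeR no gene passed the threshold: the adjusted p was 0.0544 for il11a, 0.0837 for vegfaa and 0.169 for adrb2b. All 3 passed with DESeq2, at adjusted p of 1.38e-12, 1.19e-06 and 2.09e-06, and with weighted limma-voom at 0.0177 each. Il11a also passed in edgeR when wild type replicate 4 was left out (-3.02, adjusted p = 0.0165).

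Across all tested genes, edgeR called 0 higher and 0 lower at an adjusted p under 0.05, with 1236 at an unadjusted p under 0.05 (531 higher and 705 lower in the mutant), where chance gives 947. Weighted limma-voom called 0 higher and 7 lower, and DESeq2 called 52 higher and 88 lower. With the replicate number as a block edgeR again called 0, while 2441 genes had an unadjusted p under 0.05. Without both replicates 3, 2285 genes did and edgeR called 0, while DESeq2 called 107 higher and 272 lower. Mutant and wild-type libraries did not overlap for 259 genes (128 higher, 131 lower); chance gives 0.794% of genes, which is 150. Leaving out wild type replicate 3 gave 1913 genes at an unadjusted p under 0.05, and leaving out mutant replicate 4 gave 780.

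The other lower genes that the naming rule picks, which takes genes with a given name and a mean log2 CPM over 1, had edgeR adjusted p between 0.374 and 0.396, and DESeq2 called each of them. They included epoa, encoding erythropoietin (190 ± 46.4 CPM in wild type, 101 ± 17.4 CPM in the mutant, -0.91 ± 0.19), and kcne4, a potassium channel subunit (125 CPM and 38.2 CPM, -1.71 ± 0.35). Further ones were coq10b, a coenzyme Q binding protein (366 ± 105 CPM and 163 ± 41.0 CPM, -1.17 ± 0.24), opa3 (15.3 ± 2.11 CPM and 9.20 ± 0.78 CPM, -0.74 ± 0.14) and hsd17b8, which acts in mitochondrial fatty acid synthesis (11.98 ± 5.89 CPM and 1.95 ± 1.16 CPM, -2.62 ± 0.50). Pdlim5a, a Z-disc protein, was at 16.3 ± 5.59 CPM and 6.30 ± 1.71 CPM. The kinase gene sgk2b was at 118 ± 33.8 CPM and 47.4 ± 19.5 CPM, the chromatin remodeller gene chd5 at 17.3 ± 4.04 CPM and 9.69 ± 0.93 CPM, and the tapasin gene tapbp.1 at 25.3 ± 6.34 CPM and 10.4 ± 2.65 CPM. Of these genes, hsd17b8 and tapbp.1 lie on chromosome 19 between 7 and 7.3 Mb, in the cluster described below. The ranges of the groups overlapped for kcne4 only. Lower genes without a given name, outside the rule and chosen after their values were seen, had smaller p: si:rp71-1h20.9 (-1.57 ± 0.20, adjusted p = 0.0544), zgc:103438 on chromosome 19 (-2.27 ± 0.33, adjusted p = 0.0954), si:ch73-364h19.1 (adjusted p = 0.169) and si:ch211-57n23.1 (-0.95 ± 0.16, adjusted p = 0.282).

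Among genes higher in the mutant that the rule picks, mhc1uka, an MHC class I gene, had the smallest p (1.72 ± 0.96 CPM in wild type, 6.84 ± 1.70 CPM in the mutant, 1.99 ± 0.40, adjusted p = 0.374). It was followed by C19H6orf62 (39.2 ± 15.3 CPM and 91.0 ± 7.76 CPM, 1.21 ± 0.25) and myclb, a MYC family transcription factor (4.86 ± 2.65 CPM and 12.9 ± 1.92 CPM, 1.41 ± 0.32). These 3 lie on chromosome 19, as do irgf1, an immunity-related GTPase (2.77 ± 1.204 CPM and 5.72 ± 0.37 CPM), and rida (9.20 ± 3.23 CPM and 17.7 ± 2.93 CPM). On other chromosomes were vcana, the matrix proteoglycan versican (2.26 ± 0.47 CPM and 5.06 ± 1.78 CPM), gas1b, a hedgehog coreceptor (4.001 ± 0.72 CPM and 6.71 ± 0.70 CPM), and aqp7, an aquaglyceroporin (6.50 ± 1.37 CPM in wild type, 0.77 ± 0.19). Also named by the rule were rin2 (31.3 ± 5.97 CPM and 47.3 ± 5.22 CPM), anxa13l (1.15 ± 0.35 CPM and 2.94 ± 1.11 CPM) and necab2 (2.17 ± 1.41 CPM and 7.89 ± 2.84 CPM). The ferritin gene fthl28 was at 56.1 ± 14.6 CPM and 171 ± 125.9 CPM, with mutant replicate 4 alone at 388 CPM. Of genes without a given name, chosen after their values were seen, si:dkey-266f7.5 (2.51 ± 0.48) and zgc:172143 (1.26 ± 0.25) had smaller p than mhc1uka, with the same adjusted p of 0.374. The edgeR adjusted p of the genes picked by the rule reached from 0.374 to 0.522; DESeq2 called each of them except rin2, and the groups overlapped for vcana, anxa13l and rida.

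**Figure D2:**
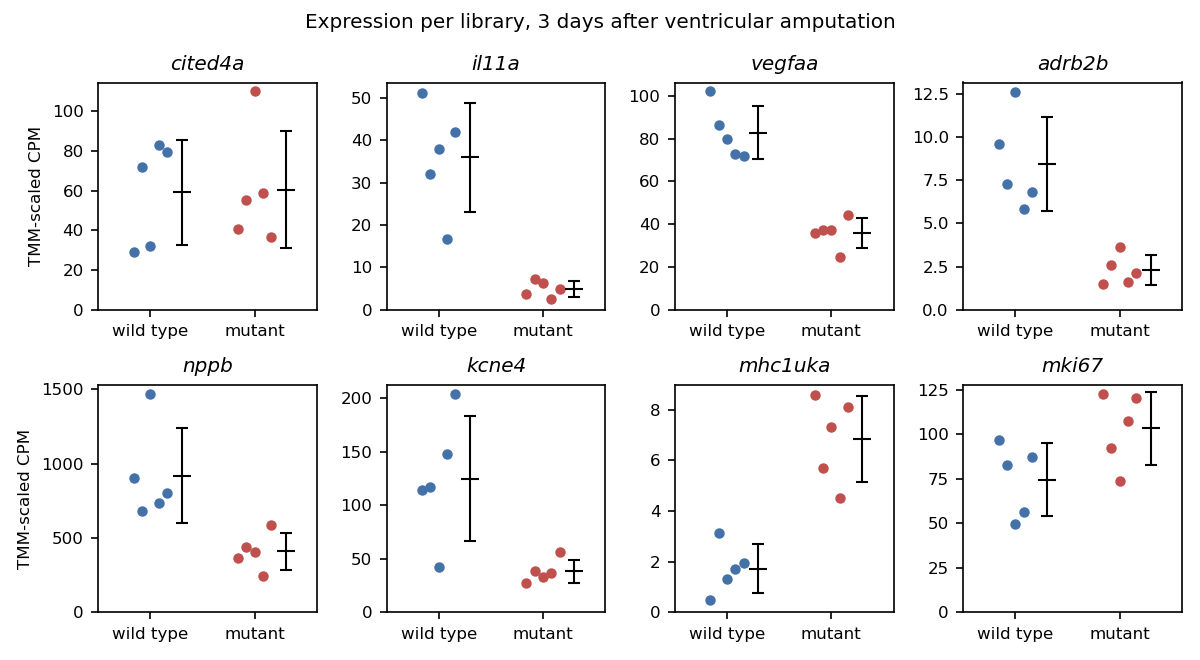
TMM-scaled CPM of 8 genes in each library, wild type in blue and cited4a mutant in red; the bar beside each group is its mean ± SD over 5 libraries. The groups did not overlap for il11a, vegfaa, adrb2b, nppb and mhc1uka, and overlapped for cited4a (59.2 and 60.3 CPM), kcne4 and mki67.

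Camera with its preset correlation called the G2/M and mitosis list higher in the mutant: 58 of 61 genes had a higher voom level, with a median change of 0.25 (camera adjusted p = 2.11e-12 with a preset correlation). The call did not hold with an estimated correlation between genes (adjusted p = 0.345). Wild type replicate 4 stood apart on this list, at a mean log2 CPM of 3.36 against 3.80 to 3.93 in the other wild-type libraries, and without it the median was 0.17 with the call kept. The list's mean level per library differed with an exact permutation p of 0.0159, which is 0.360 after adjustment over 34 lists. No member passed alone, and 12 had an unadjusted p under 0.05, all higher. Mki67, the proliferation marker, was at 74.5 ± 20.5 CPM in wild type and 103 ± 20.6 CPM in the mutant (0.47 ± 0.21, edgeR adjusted p = 0.757). Libraries of ventricles do not tell in which cell type the transcripts of this list lay, cardiomyocytes or others. The spindle factor gene tpx2 (31.3 and 41.1 CPM) and tacc3 (32.3 and 45.4 CPM) were chosen after their values were seen. The most abundant members, tuba8l4 and top2a, changed by -0.04 ± 0.25 and 0.21 ± 0.17, the first of these turning its sign without both replicates 3. In the list of S phase and DNA replication 31 of 50 genes were lower, with a median of -0.06 (adjusted p = 0.237, and 0.823 with an estimated correlation). That median was 0.07 without wild type replicate 3 and 0.08 without both replicates 3, and the list was called lower without wild type replicate 1 (-0.07, adjusted p = 0.0379) or 4 (-0.10, adjusted p = 0.00419). Pcna was at 181 ± 75.01 CPM and 165 ± 12.8 CPM, with 310 CPM in wild type replicate 3, and rrm1 at 74.5 ± 16.3 CPM and 76.5 ± 5.47 CPM.

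The sarcomere and cardiac contraction list was called lower with the preset correlation: 37 of 47 members were lower, with a median of -0.28 (camera adjusted p = 1.34e-06; adjusted p = 0.345 with an estimated correlation). The values of 9 members had an unadjusted p under 0.05, all lower, and 0 passed, also adjusted over the list alone. The cardiac myosin heavy chain myh7l was at 30020.0 ± 4482 CPM in wild type and 23820.0 ± 3389 CPM in the mutant (-0.33 ± 0.16). The regulatory light chain myl7 was at 12140.0 ± 4279 CPM and 9544 ± 1955 CPM (-0.35 ± 0.24), and the ventricular myosin myh7, formerly vmhc, at 1285 ± 247 CPM and 953 ± 280 CPM (-0.43 ± 0.21). Calcium handling and cardiac excitation genes had a median of -0.17, with 21 of 27 lower (adjusted p = 0.0272; adjusted p = 0.452 with an estimated correlation). That call ended without wild type replicate 4 (median -0.055, adjusted p = 0.195), mutant replicate 1 (-0.14, 0.175) or mutant replicate 5 (-0.093, 0.0533), and the median was -0.29 without wild type replicate 3 with the call kept. The calcium pump gene atp2a2a was at 3628 ± 701 CPM and 3096 ± 770 CPM, and its inhibitor pln at 2207 ± 404 CPM and 2035 ± 426 CPM.

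The list of cardiomyocyte dedifferentiation and the injury response was likewise called lower, with 33 of 47 lower and a median of -0.17 (camera adjusted p = 2.04e-04; adjusted p = 0.345 with an estimated correlation). The median was -0.11 without wild type replicate 1 and -0.08 without mutant replicate 3, and both calls held. Nppb, a natriuretic peptide gene of stressed and fetal heart muscle, was at 919 ± 318 CPM in wild type and 410 ± 124 CPM in the mutant (-1.16 ± 0.26). It was the 1 member that passed over the list alone (adjusted p = 0.0429), against 0 members over all genes, where its edgeR adjusted p was 0.522 and its DESeq2 adjusted p 0.0143. Nppa, the other natriuretic peptide, was at 2547 ± 548 CPM and 1723 ± 355 CPM (-0.56 ± 0.19). The filamin gene flnca changed by -0.02 ± 0.27. Of the transcription factors always named, gata4 was at 29.7 ± 14.9 CPM and 28.6 ± 8.91 CPM, and runx1 at 14.2 ± 7.26 CPM and 11.9 ± 5.95 CPM. Gata4 was at 3.77 CPM in wild type replicate 3 and 13.1 CPM in mutant replicate 3.

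Of the energy metabolism lists, 4 of nuclear-encoded genes were called lower with the preset correlation and 0 with an estimated one. In the mutant, 79 of 80 nuclear-encoded oxidative phosphorylation genes were lower (median -0.42), as were 35 of 38 fatty acid oxidation genes (-0.41), 41 of 50 glycolysis and lactate genes (-0.36) and 21 of 24 TCA cycle genes (-0.31). Camera adjusted p, in the same order, were 1.84e-20, 2.09e-12, 2.04e-09 and 7.04e-06, and with an estimated correlation the adjusted p were 0.480, 0.345, 0.345 and 0.375. No member passed over all genes or adjusted over the list alone. Members with an unadjusted p under 0.05 numbered 9, 9, 13 and 4, and all were lower. The ATP synthase genes atp5f1b (3676 ± 1061 CPM and 2803 ± 632 CPM) and atp5fa1 (2883 ± 895 CPM and 2172 ± 546 CPM) were the most abundant of the first list. In fatty acid oxidation acadvl was at 1343 ± 473 CPM and 976 ± 318 CPM, and acsl1b at 700.0 ± 309 CPM and 484 ± 164 CPM. The most abundant glycolytic genes went the other way in value, gapdh at 0.23 ± 0.25 and aldoaa at 0.07 ± 0.20. In the TCA cycle mdh2 changed by -0.05 ± 0.20 and idh2 by -0.31 ± 0.24. Leaving out wild type replicate 3, which had the highest oxidative phosphorylation level of all libraries, brought that list's median to -0.21 and the TCA cycle median to -0.20, with both calls kept. The 13 mitochondrially encoded mRNAs were all lower, with a median of -0.20 (adjusted p = 0.0267; adjusted p = 0.733 with an estimated correlation). This call ended without wild type replicate 3 (median -0.02, adjusted p = 0.580), mutant replicate 1 (-0.08, 0.406) or mutant replicate 5 (-0.10, 0.265), while the median was -0.46 without mutant replicate 3. Their most abundant members were mt-co1 at 39610.0 ± 6422 CPM and 35810.0 ± 12220.0 CPM and mt-co3 at 18070.0 ± 5751 CPM and 17210.0 ± 7114 CPM.

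The list of hypoxia-inducible factor (HIF) targets was called lower with the preset correlation, with 27 of 39 lower and a median of -0.23 (camera adjusted p = 7.04e-06; adjusted p = 0.345 with an estimated correlation). Here 10 members passed adjusted over the list alone, all lower, against 0 over all genes. They were vegfaa, epoa, vegfab, pfkfb3, egln3, bnip3lb, errfi1a, tfr1b, ldha and ndrg1a. Of those chosen after their values were seen, the prolyl hydroxylase gene egln3 was at 48.4 ± 18.5 CPM in wild type and 16.1 ± 7.73 CPM in the mutant (-1.59 ± 0.39). The glycolytic regulator gene pfkfb3 was at 63.8 ± 10.9 CPM and 30.3 ± 12.3 CPM (-1.08 ± 0.28), and vegfab, a further vascular endothelial growth factor, at 268 ± 40.4 CPM and 158 ± 51.7 CPM (-0.76 ± 0.21). The most abundant members were ldha, the lactate dehydrogenase gene, at 1416 ± 269 CPM and 964 ± 116 CPM with no overlap between groups, and hif1ab at 349 ± 78.0 CPM and 286 ± 54.2 CPM. The list's median was -0.04 without wild type replicate 4 and -0.15 without wild type replicate 5, with the call kept in both, -0.35 without wild type replicate 3 and -0.37 without both replicates 3.

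Of the marker lists of other cell types, 3 passed with the preset correlation. Fibroblast and extracellular matrix genes were called higher, with 41 of 53 higher and a median of 0.24 (camera adjusted p = 4.32e-05; adjusted p = 0.538 with an estimated correlation), or 0.12 without mutant replicate 4. Adjusted over the list alone, vcana passed as higher and nppc, which encodes a natriuretic peptide (11.2 and 2.77 CPM), as lower. Col1a1b, a chain of type I collagen, was at 2610.0 ± 546 CPM and 3585 ± 868 CPM, and fn1b, a fibronectin gene, at 3228 ± 420 CPM and 2963 ± 721 CPM. Lymphocyte genes had a median of 0.30 (28 of 38 higher, adjusted p = 0.0202; adjusted p = 0.472 with an estimated correlation). The call ended without wild type replicate 1 (0.0790) or 5 (0.0780), and without mutant replicate 1 (0.175) or 3 (0.127), as well as without both replicates 3 (median 0.21, 0.105). The chemokine receptor gene ccr9a was at 26.2 ± 7.398 CPM and 43.3 ± 7.03 CPM with no overlap between groups, and jak3 at 10.2 ± 2.64 CPM and 13.5 ± 2.30 CPM. Erythrocyte genes had a median of 0.23 (19 of 28 higher, adjusted p = 0.0273; adjusted p = 0.716 with an estimated correlation). Without mutant replicate 5 that median was 0.02 (adjusted p = 0.814), and the call was also lost without wild type replicate 1, 3, 4 or 5 and without mutant replicate 1 or 3, and without both replicates 3 (median 0.20, adjusted p = 0.111). The globin genes hbaa1 and hbba1 (ENSDARG00000089087) changed by 0.05 ± 0.28 and 0.85 ± 0.32.

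The remaining cell type lists did not pass. Endocardium and endothelium had a median of 0.01 while camera's direction was down (adjusted p = 0.711), with cav1 at 588 ± 123 CPM and 512 ± 94.9 CPM and podxl at 572 ± 78.5 CPM and 467 ± 23.0 CPM. Of its members dll4, a Notch ligand gene, passed adjusted over the list alone (75.8 ± 20.1 CPM and 45.6 ± 2.94 CPM, -0.73 ± 0.16). The epicardium list had a median of 0.10 (0.596), and its abundant member krt8 changed by 0.06 ± 0.14. Leaving out single libraries moved that median between 0.028 (mutant replicate 5) and 0.17 (mutant replicate 3). Smooth muscle, mural and outflow tract genes had a median of -0.21 (0.0591), with abcc9 at -0.49 ± 0.32 and tagln at -0.48 ± 0.29. That list was called lower without wild type replicate 1 (-0.21, 0.0214) or 3 (-0.21, 0.0137) and without mutant replicate 2 (-0.28, 0.0119), 4 (-0.18, 0.0395) or 5 (-0.26, 0.0230). Its median was only -0.027 (0.598) without mutant replicate 3 and -0.13 (0.225) without wild type replicate 5, and with an estimated correlation the adjusted p was 0.700. Atrial cardiomyocyte genes had 0.28 (0.471), between 0.11 (wild type replicate 1) and 0.42 (wild type replicate 2) when single libraries were left out: myh6 ranged from 13.1 to 394 CPM in wild type and from 40.7 to 376 CPM in the mutant, and bmp10l was at 73.6 ± 19.9 CPM and 48.6 ± 16.98 CPM. Macrophage genes had 0.12 (0.0939; 0.0149 with the replicate block, and 0.552 with the block and an estimated correlation), with fabp11a at -0.35 ± 0.25 and lgmn at 0.46 ± 0.18. Their median was 0.016 without wild type replicate 4, and the list was called higher without wild type replicate 1 (0.18, 0.0468), 2 (0.15, 0.0361) or 3 (0.11, 0.0489) and without mutant replicate 2 (0.10, 0.0478) or 4 (0.20, 0.00127). For thrombocytes the median was 0.16 (0.1003), with tln1 at 0.07 ± 0.18 and vwf at 0.32 ± 0.18. With the block the adjusted p was 0.0252, and 0.563 with the block and an estimated correlation, while the median was 0.076 without mutant replicate 1 and 0.31 (0.00424) without mutant replicate 4. Neutrophil genes had -0.06 (0.814), with s100a10b at -0.23 ± 0.24 and cebpd at -0.26 ± 0.55. Lists named for other tissues likewise did not pass: liver and plasma proteins at 0.23 (0.657; tfa at 0.37 ± 0.29, rbp4 at -0.37 ± 0.33), skeletal muscle at -0.11 (0.402; mb at -0.45 ± 0.23, ckma at -0.07 ± 0.21), and neurons and glia at -0.09 (0.604; gfra3 at -0.29 ± 0.21, syt1a at -0.91 ± 0.94). Mb ranged from 15180 to 25730 CPM and ckma from 1468 to 2305 CPM in wild-type ventricles, so the skeletal muscle list does not measure that tissue alone.

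Immediate-early genes were called lower as a list with the preset correlation, with a median of -0.48 and 29 of 35 lower (camera adjusted p = 1.34e-05; adjusted p = 0.423 with an estimated correlation). Of its members 9 had an unadjusted p under 0.05, all lower, and 0 passed, also adjusted over the list alone. Ccn1 was at 236 ± 98.2 CPM in wild type and 164 ± 32.4 CPM in the mutant, and klf6a at 209 ± 54.4 CPM and 147 ± 30.1 CPM. Heat shock and unfolded protein response genes were also called lower (median -0.22, 35 of 48 lower, adjusted p = 2.45e-04; adjusted p = 0.469 with an estimated correlation). Hspb1 was at 1457 ± 734 CPM and 999 ± 306 CPM, and hsp90ab1 changed by -0.03 ± 0.12. Inflammatory cytokines and chemokines as a list did not pass (median -0.07, adjusted p = 0.104), but were called lower without wild type replicate 4 (-0.19, adjusted p = 0.00833). Their median was -0.001 without mutant replicate 4 and -0.003 without both replicates 3, and with an estimated correlation the adjusted p was 0.642. Il11a alone passed adjusted over the list alone. The cytokine feedback inhibitors socs3a and socs3b were at 641 ± 461 CPM and 359 ± 108 CPM, and at 304 ± 179 CPM and 133 ± 37.5 CPM. The interferon response and antigen presentation list had a median of 0.18 and a mean change of -0.21, with camera's direction up (adjusted p = 0.0629, and 0.716 with an estimated correlation). With the replicate block the adjusted p was 0.0435, and 0.658 with the block and an estimated correlation. The list was called higher without its chromosome 19 genes (median 0.23, adjusted p = 5.78e-05), without wild type replicate 1 (0.23, 0.00380) or 2 (0.22, 0.0405) and without mutant replicate 2 (0.21, 0.00481). Fry's test for change in either direction gave an adjusted p of 0.0357. Adjusted over the list alone, mhc1uka and rsad2 passed as higher, and tapbp.1, psmb8a, psmb9a, psmb12 and psmb13a as lower. The abundant members b2ml and b2m changed by 0.21 ± 0.15 and 0.06 ± 0.19.

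The growth factor and regeneration signals list had a median of 0.10 (adjusted p = 0.957) in the voom values and -0.01 in edgeR. Its members vegfaa and dll4 passed adjusted over the list alone, while mdka changed by 0.28 ± 0.18 and notch1b by 0.09 ± 0.43. The p53, apoptosis and CDK inhibitors list had a median of 0.08 and a mean near 0 (adjusted p = 0.957), with btg1 at 0.06 ± 0.15 and ccng1 at 0.08 ± 0.22. Cholesterol and lipid synthesis had -0.04 (0.484; acacb at -0.05 ± 0.28, srebf2 at -0.16 ± 0.17). Pentose phosphate, serine and nucleotide synthesis had -0.05 (0.596; nme2b.1 at -0.12 ± 0.17, nme2b.2 at -2.36 ± 0.87 with 21.9 to 676 CPM in wild type). Cytosolic ribosomal protein genes were called lower by a small amount that rested on wild type replicate 3: 82 of 83 were lower, with a median of -0.12 (adjusted p = 3.61e-05; adjusted p = 0.733 with an estimated correlation). Their median was 0.06 without wild type replicate 3 (adjusted p = 0.0852), -0.016 without both replicates 3 (adjusted p = 0.295), -0.18 without wild type replicate 2 and -0.20 without mutant replicate 3, and rps2 and rplp0 changed by -0.19 ± 0.19 and -0.18 ± 0.19. In all, camera with its preset correlation of 0.01 called 12 of the 34 lists lower and 4 higher, and none held with an estimated correlation, by fry's directional test or by exact permutation of the list means.

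**Figure D3:**
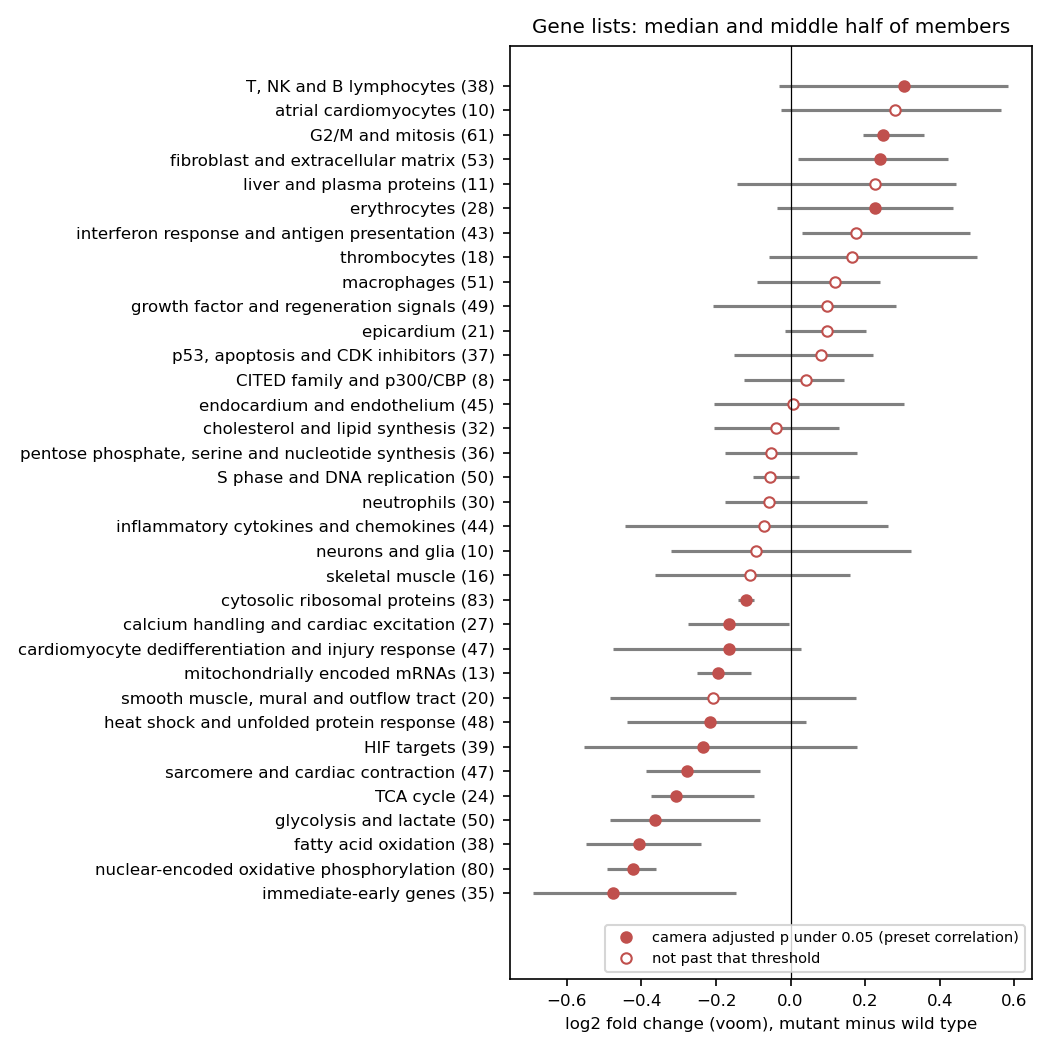
Median (point) and range from the first to the third quartile (line) of the voom log2 fold changes, mutant minus wild type, of the members of the 34 gene lists, with the number of members in brackets. Filled points passed camera at an adjusted p under 0.05 with the preset correlation of 0.01, under which immediate-early genes lie at -0.48 and G2/M and mitosis lies at 0.25.

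Chromosome 19, which carries cited4a, held more genes with low p-values than other chromosomes. Of its 731 tested genes 88 had an unadjusted p under 0.05, which is 12% against 6.30% elsewhere (Fisher's exact test, two-sided p = 2.50e-08, adjusted over 25 chromosomes 6.25e-07). The next was chromosome 7 with 9.05% (adjusted p = 0.0187). The planned test of called genes within 5 Mb of cited4a had nothing to count, since edgeR called 0 genes; DESeq2 called 2 of the 121 there. Tests with the unadjusted p were chosen after that was known. Within 5 Mb, 13 of 121 genes had an unadjusted p under 0.05 (10.7% against 6.50%, Fisher's exact p = 0.0646), within 10 Mb 39 of 292 (13.4% against 6.42%, Fisher's exact p = 2.03e-05), and within 2 Mb 2 of 30. The region within 10 Mb includes the gene cluster between 7 and 7.3 Mb described below, while that within 5 Mb does not. Of 279 windows of 5 Mb, 6 passed, of which 2 were on chromosome 19, from 30 to 35 Mb (17 of 78 genes, adjusted p = 0.00123) and from 5 to 10 Mb (19 of 107). A window on chromosome 7 from 5 to 10 Mb had the same counts and p as the first of these, and the others were on chromosomes 3, 10 and 13. The window of chromosome 19 from 5 to 10 Mb holds a cluster of antigen-processing genes between 7 and 7.3 Mb, where of 17 tested genes 7 were lower and 1 was higher in every mutant library. Psmb8a, an immunoproteasome subunit gene, was at 45.6 ± 13.1 CPM in wild type and 5.97 ± 4.92 CPM in the mutant. It had 0 counts in mutant replicate 5, as had its neighbours psmb9a, psmb12, psmb13a and the peptide transporter gene tap2a. The levels of daxx, tapbp.2, brd2a and sdha, which lie in the same stretch, overlapped between groups. The genes of this stretch were chosen after their values were seen.

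The deposited comparison by the authors, made with DESeq2, lists 20292 genes and leaves out both replicates 3. Its fold changes are signed as wild type over mutant, the reverse of the sign used here: across 18946 shared genes Pearson's r with the edgeR changes was -0.915 and Spearman's rho -0.876, where genes are not independent replicates. It calls 419 genes at an adjusted p under 0.05, 303 lower and 116 higher in the mutant. Of the 140 genes that DESeq2 called here on 10 libraries, 111 were among them, all in the same direction. Of the 402 deposited calls that edgeR tested, 401 had the same direction and 288 an unadjusted p under 0.05. In the deposited table il11a has an adjusted p of 3.20e-11, kcne4 2.45e-09, vegfaa 2.50e-06, cited2 2.42e-06 and nppb 0.0146, while cited4a has 0.540 and mki67 0.205.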

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

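Each value below stood far from the other 4 libraries of its group, by a gap test whose limit was set before the data were examined. Of 274 groups tested 36 had such a library, where chance gives 13.7, and 22 of them were in wild type replicate 3. Levels are CPM unless a mean log2 CPM is given, with the range of the other 4 libraries of the group in brackets.

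In wild type replicate 3 the mitochondrial share was 17.2% (12.8% to 13.6%), mt-co3 was at 28320.0 (14940.0 to 16150.0) and the mean log2 CPM of the mitochondrially encoded mRNAs was 13.31 (12.46 to 12.66). Transcripts of the translation machinery were high there: rps2 at 4783 (2505 to 2927), rplp0 at 4277 (2214 to 2556), and the cytosolic ribosomal protein list at 9.97 (9.05 to 9.21). So were the small heat shock gene hspb1 at 2757 (999.9 to 1278), the transcription factor gene cebpd at 579 (68.6 to 144), s100a10b at 1377 (554 to 718), tagln at 362 (127 to 181), fabp11a at 1673 (713 to 977), pcna at 310 (128 to 177) and nppb at 1468 (681 to 906). Further high values were hbaa1 at 6567 (2612 to 3739), nme2b.1 at 945 (595 to 612), ep300b at 63.1 (51.6 to 54.7) and the neurons and glia list at 1.87 (0.82 to 0.96). Low values in this library were gata4 at 3.77 (32.9 to 41.4), notch1b at 43.0 (291 to 378), flnca at 1040.0 (2144 to 2409), tln1 at 301 (463 to 505) and the HIF target list at 4.42 (5.09 to 5.35).

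Mutant replicate 3 had 5 such values, of which gata4 at 13.1 (30 to 34.99), hspb1 at 1543 (833 to 918) and rplp0 at 2859 (2263 to 2423) went the same way as in wild type replicate 3. The others were nppa at 2338 (1433 to 1676) and the oxidative phosphorylation list at 7.97 (7.04 to 7.302). Mutant replicate 4 had 4: fthl28 at 388 (80.4 to 154), lgmn at 1143 (729.8 to 829.8), mdka at 2048 (1097 to 1368) and rrm1 at 67.0 (77.4 to 80.4). In mutant replicate 1 jak3 was at 17.45 (11.8 to 13.2) and ckma at 1024 (1921 to 2145), and in mutant replicate 2 chd5 was at 11.3 (9.02 to 9.60). Myh6, an atrial myosin gene, was at 394 in wild type replicate 2 (13.1 to 98.8), and the G2/M and mitosis list was at 3.36 in wild type replicate 4 (3.80 to 3.93).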

How the results depend on the processing

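The fits on 8 libraries without both replicates 3, the exact permutation of list means, the replicate block combined with an estimated correlation or with fry, and counts at an unadjusted p were chosen after the results were seen; the other alternatives were planned. Where a value below differs from the report, the cause was not tested unless stated.

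Il11a kept its direction in each alternative, with a change between -3.02 and -2.68 when single libraries were left out and an edgeR adjusted p between 0.0165 and 0.165 there. Over the named genes and cited4a, 1950 comparisons with an alternative kept direction and side of the threshold, 34 passed the threshold with the same direction and 70 changed sign. DESeq2 called 24 of the 98 named genes, weighted limma-voom 4 (il11a, vegfaa, adrb2b and kcne4) and the fit with 1 surrogate variable 2 (il11a and adrb2b). Il11a alone of them passed with RLE scaling, with no filter, with the CPM filter and without wild type replicate 4. For the lists, 700 comparisons kept direction and call, 108 lost the call, 31 gained it and 44 changed direction.

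Against 0 genes called by edgeR and 1236 at an unadjusted p under 0.05, DESeq2 called 52 higher and 88 lower with 1864 at that p, weighted limma-voom 0 and 7 with 2339, and 1 surrogate variable 0 and 4 with 2520. Genes called lower were 2 with RLE scaling, 1 with no filter and 2 with the CPM filter, and 0 were called higher in each. The replicate block gave 0 calls (smallest adjusted p = 0.0588) and 2441 genes at an unadjusted p under 0.05. On 8 libraries edgeR called 0, with 2285 at that p, DESeq2 called 107 higher and 272 lower with 2791, and DESeq2 on the genes the authors list 114 and 304 with 2767. Leaving out single libraries gave 0 to 1 genes called lower (1 without wild type replicate 4), 0 called higher, and from 780 (without mutant replicate 4) to 1913 (without wild type replicate 3) at an unadjusted p under 0.05. Within 5 Mb of cited4a, DESeq2 called 2 genes, or 7 on 8 libraries and 8 on the genes of the authors' table, and 13 had an unadjusted p under 0.05, where edgeR called 0. The median gene had a biological coefficient of variation of 0.32, and edgeR made calls on simulated counts of the same size and depth. What depth limits was not tested by drawing fewer reads, so its effect on genes at low counts is not known here.

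Camera with its preset correlation called 16 lists, and between 12 and 19 when scaling, filter, block, surrogate variable, weights, gene set or libraries changed. With an estimated correlation, fry, exact permutation of list means, and the replicate block with either an estimated correlation or fry, 0 lists were called. In the first 2 of these settings G2/M and mitosis had a median of 0.247, sarcomere and cardiac contraction -0.278 and cardiomyocyte dedifferentiation and injury response -0.167, with adjusted p of 0.345 and 0.315. By exact permutation the mean differences were 0.275, -0.235 and -0.271, with adjusted p from 0.360 to 0.386. With the block the medians were 0.246, -0.28 and -0.167, with adjusted p of 0.445 with an estimated correlation and 0.134 to 0.173 with fry. Camera with an estimated correlation differs from the preset in how the correlation is set and also in using fewer degrees of freedom. With both changed, the 16 calls went to 0, and their effects were not told apart. The estimate was 0.288 for G2/M and mitosis, 0.159 for sarcomere and cardiac contraction, 0.027 for cardiomyocyte dedifferentiation and 0.914 for oxidative phosphorylation, against 0.01. The other settings also differ in more than 1 choice. Fry and the permutation test a list against no change and not against other genes, and the block changes the design. The loss of calls was not traced to any 1 choice in any of these settings. On 8 libraries with the preset, lymphocytes (adjusted p = 0.105), erythrocytes (0.111) and cytosolic ribosomal proteins (0.295) lost their calls. The replicate block alone added macrophages (adjusted p = 0.0149), thrombocytes (0.0252) and interferon response and antigen presentation (0.0435), none of which held when the block was combined with an estimated correlation (0.552, 0.563 and 0.658). The fit that was not robust has no list values, since camera has no such setting.

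Direction changed for these values, none of them past the threshold in the setting named. For lists the direction is camera's, or the sign of the mean difference for the exact permutation. It changed for growth factor and regeneration signals on 8 libraries, with upper-quartile scaling and with the CPM filter while the median stayed above 0. With weighted limma-voom: cited4a -0.30, pcna 0.078, tuba8l4 0.155, s100a10b 0.016, cebpd 0.275, srebf2 0.001, and the lists CITED family and p300/CBP -0.14, S phase and DNA replication 0.044, neutrophils 0.039, neurons and glia 0.01, and pentose phosphate, serine and nucleotide synthesis 0.046. On 8 libraries: cited4a -0.46, pcna 0.11, tuba8l4 0.15, fn1b 0.027, s100a10b 0.026, cebpd 0.28, notch1b -0.061, btg1 -0.015, ccng1 -0.011, and the lists CITED family and p300/CBP -0.10, S phase and DNA replication 0.081, neutrophils 0.037, growth factor and regeneration signals 0.001, neurons and glia 0.038, and pentose phosphate, serine and nucleotide synthesis 0.038. With the replicate block: tuba8l4 0.027, cebpd 0.007 and gata4 0.20. With 1 surrogate variable: tuba8l4 0.07, cebpd 0.175, gata4 0.054 and the CITED family list -0.007. With upper-quartile scaling: flnca 0.011, hsp90ab1 0.001 and growth factor and regeneration signals 0.13. With the CPM filter growth factor and regeneration signals was at 0.054, and with DESeq2 it was at -0.022 and the CITED family list at -0.004. By exact permutation of list means, endocardium and endothelium was at 0.017, interferon response and antigen presentation at -0.15 and p53, apoptosis and CDK inhibitors at -0.001.

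Leaving out 1 library at a time also changed the direction of some values, given here from lowest to highest. Genes: cited4a -0.31 to 0.18, pcna -0.23 to 0.15, rrm1 -0.036 to 0.14, tuba8l4 -0.18 to 0.21, flnca -0.19 to 0.14, aldoaa -0.026 to 0.20, mdh2 -0.18 to 0.048, mt-co3 -0.35 to 0.15, fn1b -0.23 to 0.003, krt8 -0.005 to 0.13, s100a10b -0.33 to 0.073, cebpd -0.57 to 0.59, hbaa1 -0.058 to 0.33, tln1 -0.037 to 0.17, b2m -0.049 to 0.23, notch1b -0.19 to 0.23, ccng1 -0.08 to 0.17, hsp90ab1 -0.061 to 0.013, ckma -0.16 to 0.076, acacb -0.22 to 0.09, nme2b.1 -0.20 to 0.037, rps2 -0.26 to 0.016, rplp0 -0.25 to 0.025 and gata4 -0.34 to 0.13. Lists: CITED family and p300/CBP -0.20 to 0.10, S phase and DNA replication -0.097 to 0.067, endocardium and endothelium -0.10 to 0.056, neutrophils -0.12 to 0.092, growth factor and regeneration signals -0.075 to 0.14, p53, apoptosis and CDK inhibitors 0.032 to 0.11, liver and plasma proteins 0.005 to 0.35, skeletal muscle -0.18 to 0.058, neurons and glia -0.14 to 0.027, pentose phosphate, serine and nucleotide synthesis -0.11 to 0.055, and cytosolic ribosomal proteins -0.20 to 0.057. The direction of a list is camera's here, and for p53 and liver lists it changed while the median stayed above 0. The median alone turned for cholesterol and lipid synthesis (0.042 without mutant replicate 4, 0.004 with weighted limma-voom), for neurons and glia (0.003 with DESeq2) and for endocardium and endothelium (-0.028 with DESeq2, -0.012 with weighted limma-voom, -0.009 with RLE scaling, -0.027 on 8 libraries). Without wild type replicate 3 the sign turned for 13 named genes, more than without any other library. S phase and DNA replication was called lower without wild type replicate 1 (-0.07, adjusted p = 0.0379) or 4 (-0.10, adjusted p = 0.00419).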

Other observations

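The tests of the cardiomyocyte share, the test of variants linked to the allele and the test of interferon signalling were chosen after the results they concern were seen, as were all tests at an unadjusted p and the fits on 8 libraries.

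Further single genes with a low unadjusted p were chosen by hand after their values were seen, none past the threshold in edgeR, and no test was made of them as groups. The heat shock genes hsp70.1, hsp70.2 and hsp70.3 were at 16.9, 25.5 and 19.1 CPM in wild type and 6.87, 10.6 and 7.13 CPM in the mutant, and hsp90aa1.1 at 610 and 327 CPM. The transcription factor genes klf2a and klf2b were at 27.6 and 83.8 CPM in wild type and 14.8 and 36.3 CPM in the mutant, and flt1, a receptor of vascular endothelial growth factor, at 70.29 and 39.3 CPM, while the endothelium list that holds them had a median of 0.01. Ptgs2b, which encodes a cyclooxygenase that makes prostaglandins, was at 32.8 and 9.26 CPM (-1.83 ± 0.54), and the nuclear receptor gene nr4a3 at 93.0 ± 80.9 and 15.6 ± 10.9 CPM (-2.57 ± 0.71). Esrra, also a nuclear receptor gene, was at 67.0 ± 35.6 and 32.2 ± 6.46 CPM. Haem oxygenase hmox1a went the other way, from 179 to 349 CPM (0.97 ± 0.26), as did the chemokine gene cxcl12a, from 69.1 to 123 CPM (0.84 ± 0.27).

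Within the sarcomere list, the Z-disc gene tcap was at 241 ± 175 CPM in wild type and 95.7 ± 40.7 CPM in the mutant, and the actin gene acta1b at 2419 ± 1223 and 1341 ± 423 CPM. The early cardiac transcription factor gene nkx2.5 was at 23.6 ± 28.5 and 2.33 ± 0.80 CPM (-3.34 ± 0.91, DESeq2 adjusted p = 0.0397). That mean rested on wild type replicates 4 and 5, at 46.3 and 61.9 CPM, while the other wild-type libraries lay between 2.56 and 3.88 CPM. Actc1a (ENSDARG00000076126) on chromosome 19 was likewise uneven, at 165 ± 161 and 26.8 ± 7.27 CPM.

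Whether other splits of the libraries give as much was counted over 100 random splits into 5 and 5, the real one among them. The count of DESeq2 calls was reached in 4 of 100 splits, the real one included (140 genes, highest other 215). That share is under 0.05 when pairs are disregarded. It does not exclude chance, since not all possible splits were run and the share was not adjusted over the several counts tried. Nor was chance excluded for the genes at an unadjusted p under 0.05 (23 of 100, with 1236 genes and 2553 in the highest other). The same held for genes whose groups do not overlap (21 of 100, with 259 and 575). It also held for lists called by camera (10 of 100, with 16 and 19). If the replicate numbers pair the samples, as was taken from the values and only weakly for replicates 2 and 5, 13 of these splits are the closer comparison. Those 13 part all 5 pairs. Only 16 such splits exist, with a smallest possible share of 0.0625, too few for a share under 0.05. The real one was the highest of these in genes at an unadjusted p (next 810), in DESeq2 calls (next 25) and in separated genes (next 123), while 3 of the 13, the real one included, called as many lists. The other 87 splits put at least 1 pair of the same number into the same group, so that differences between replicate numbers enter their counts, a structure of the samples other than genotype.

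The lower levels of metabolism and sarcomere lists were weighed against gene length, the replicate 3 libraries and the share of cardiomyocyte RNA. The edgeR median of oxidative phosphorylation genes was -0.47, below each of 10000 lists matched on length and level (percentile 0). The matched medians had a middle value of -0.12 and a lowest of -0.24. In the fit with the replicate block the list's median was -0.42, with a lowest matched median of -0.20 (percentile 0). Genes of like length and level were thus lower too, but by less, which argues against gene length bias as the whole cause. Matched members were drawn independently, while the list's genes move together (estimated correlation 0.914), so the percentile is not a p-value. Without both replicates 3 the median was -0.37, with a standard error of 0.116 for the list's mean difference, which goes beyond the bound of -0.24 set for this test (0.5 of the full median) by little more than 1 standard error and argues against those libraries as the whole cause, though wild type replicate 3 alone held part of it (-0.21 without it, in the voom values). A lower share of cardiomyocyte RNA cannot be told apart from lower expression per cell: the fibroblast list's change exceeded that of the endothelium list by 0.198 (exact permutation p = 0.151) and that of the smooth muscle list by 0.421 (exact permutation p = 0.0159, but 0.198 adjusted over all 45 pairs of cell type lists), each in 5 of 5 replicate pairs, where sign flips cannot give a p under 0.0625. A change of metabolism or of cell makeup in the mutant may underlie the lists, and neither is settled, since no list held with an estimated correlation (0 lists called).

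The excess of low p-values on chromosome 19 was reached in 5 of 100 splits as a ratio of shares (1.91, highest other 3.585), and in 3 of the 13 that part all pairs. Chance was thus not excluded. The other splits among those 5 had 157 to 474 genes at an unadjusted p under 0.05, against 1236 in the real one. Their ratios therefore rest on fewer genes, and the comparison is not of like with like. Without unnamed genes and without the stretch from 5 to 10 Mb the excess remained, at 10.4% against 6.28% (Fisher's exact p = 0.000495), so unnamed loci and that stretch did not hold all of it. Named members of gene families elsewhere on the chromosome were kept, so multigene families as a source were not excluded. Fisher's test also takes genes as independent, which genes measured in the same libraries are not. If variants linked to the allele were the cause, shares should be highest near cited4a, but they were 10.7% within 5 Mb and 12.3% on the rest of the chromosome (Fisher's exact p = 0.760); this cannot be told apart from a linked haplotype that spans most of the chromosome. For the antigen-processing genes near 7.1 Mb, lower interferon signalling was argued against by the 34 other interferon genes on other chromosomes. Their mean change was 0.318 with a standard error of 0.159, above a bound of -1 that was set after the values were seen. A different haplotype of this cluster in the mutant fish is a candidate explanation that was not tested here, without sequence reads: 5 genes had 0 counts in mutant replicate 5 and 0.76 to 11.5 CPM in the other 4 mutant libraries, and neighbours such as daxx and sdha had overlapping ranges. Levels in this stretch also varied within wild type, where mhc1uba ranged from 41.8 to 854 CPM, against 191.7 to 286.5 CPM in the mutant.

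Il11a was weighed against the state of the tissue at collection, as its level could follow the immediate-early genes, which were also lower. With the mean level of the immediate-early list as a covariate its change was -2.32 ± 0.29, against -2.84 ± 0.34 without, in edgeR, which argues against that explanation as the whole cause. Its level was lower in 5 of 5 mutant libraries than in any wild-type library. A lower level of il11a in the mutant at 3 days stays a hypothesis, since its adjusted p of 0.0544 in the planned edgeR test was above the threshold. Whether it passed depended on the fit. It did with DESeq2 (adjusted p = 1.38e-12) and weighted limma-voom (0.0177), and did not in edgeR with the replicate block (0.0588) or upper-quartile scaling (0.0611). Whether a response to injury differs was not measured, as all libraries come from injured hearts.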
